A study of Mus musculus with 9 samples.

How the data were processed

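Messenger RNA was sequenced from cultured mouse cells that the labels describe as neurospheres of dorsal root ganglion and nerve root, isolated at embryonic day 13.5 and called Schwann cell precursors in the design text. The 9 libraries fall into 3 groups of 3. Nf1 flox GFP control cells carried floxed Nf1 alleles and received an adenovirus encoding GFP. Nf1 null cells carried the same floxed alleles and received an adenovirus encoding Cre recombinase and GFP, and Nf1-Arf null cells carried floxed Nf1 and floxed Arf alleles and received the Cre-GFP virus. Cre recombinase cuts out the DNA between its target sites, so the floxed part of each gene is meant to be lost from infected cells. No GFP-infected culture of the Nf1-Arf genotype was among the samples analysed here. Groups were taken from the labels. The labels do not say whether the 3 libraries of a group came from separate embryos or cultures, so the p-values measure only the spread between these libraries, which may be technical.

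Per the labels' protocols, RNA was purified on columns with DNase treatment, and libraries were made from polyadenylated RNA with the KAPA mRNA HyperPrep kit from 100 ng of total RNA and 13 cycles of PCR. Per the submitters' processing notes, the tools were FastQC, Salmon 1.4.0 and DESeq2 (version not given), and the genome build was GRCm39. The deposited values are DESeq2 normalized counts, a signal per gene that is never negative: estimated reads per gene scaled for library depth. Whether the scaling also included a correction per gene, such as for transcript length, is not given in the sources used here. The table holds 51290 gene symbols in 9 columns, each matched to one library by its label, and 24981 symbols are at 0 in every library. The annotation at hand belongs to an older build, so no genome coordinates are given, and it served only for gene names, gene types and the search for shared sequence.

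Raw counts were not used. The smallest steps between low values gave the worth of a single read in each library, and with the column totals this gave about 36400000 to 42700000 reads in the GFP control libraries, 22600000, 36700000 and 23300000 in Nf1 null replicates 1, 2 and 3, and 38400000 to 47400000 in the Nf1-Arf null libraries. Between 65.8 and 75% of the low values were whole multiples of that step within a tolerance of 0.1 reads, so whole reads could not be recovered for nearly all genes and no count model was run.

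Normalized values were tested on the log2(value + 1) scale with limma 3.58.1 in R 4.3.3. This scale understates the change of genes with low values. Genes with a value of at least 10 in at least 3 libraries were kept, which left 16020. One linear model with a mean per group was fitted to all 9 libraries (6 residual degrees of freedom), with a prior variance that follows the mean level. The moderated tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p below 0.05 counted as a call. A moderated F test covered all 3 groups. Gene lists, 39 in all, had been written from general knowledge before the data were examined, and the 37 with at least 5 measured genes were tested with camera, which asks whether the genes of a list move more than the other genes, at a preset correlation of 0.01 between genes. Each list was also tested with a correlation estimated from the data and with fry, which asks whether the genes of a list move, on balance, one way. The 2 lists not tested were the melanocyte list, with 4 measured genes, and the erythroid list, with 0.

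The rule for the genes named in the text was set before the data were examined. In each comparison it takes a fixed set that includes Nf1, Cdkn2a, Cdkn2b, Trp53, Cdkn1a, Mdm2, Sox10, Ngfr, Dusp6, Spry4 and Mki67. It adds the 5 largest rises and 5 largest falls among called genes with a mean of at least 100 and no overlap between the groups, without predicted gene models and pseudogenes. From the 6 lists with the largest share of called genes it takes the 2 largest changes in the direction of most calls and the largest in the other direction, among genes with a mean of at least 20. From every other list called by camera it takes the largest change. Some genes that the rule takes are not reported here. A gene named outside this rule is said to have been chosen after its values were seen, which also holds for Malat1 and Ahcy.

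An exact 0 in such a table can be a failed estimate. Genes of general use were also at 0 in some libraries: Ahcy was at 10.7, 84.8 and 0 in the Nf1 null libraries against 1901 to 2186 in the GFP controls. A gene at 0 in every library of a group is therefore given as listed at 0, with the value of each library of that group and no fold change. To find genes whose reads another gene could share, the 31-base words of each named gene's transcripts were looked up in the transcripts of all other genes. Over 20% of the words were shared for Kpna2 (66%, mostly with Gm10184), Igf2 (63.1%), Tagln (62.2%), Rpl17 (46.1%), Lyz2 (32.8%) and Hes5 (25.7%), and their values are uncertain for that reason. H2ac12, a histone gene with many near copies, could not be looked up under its symbol and is uncertain as well. The strand setting of the quantification is not given in the sources used here, so genes that overlap an antisense gene cannot be told from it.

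The test was checked on simulated libraries of 16020 genes with known changes. It called 91% of genes changed by 1 on the log2 scale and 98% of genes changed by 2 in the simulated Nf1 null against GFP control comparison, with 5.03% false calls among all calls. It called 0 genes in the simulated Nf1-Arf null against GFP control comparison, where nothing was changed. The simulation changed a small share of genes and gave all groups the same spread. In the data the Nf1 null libraries varied most, so error rates under unequal spread were not checked. No 2 libraries of a group were copies of each other: their squared differences were 5.47 to 27.8 times what counting noise alone would give. Alternatives covered the pseudocount, the filter, total-sum and quantile scaling, the variance prior, sample weights, the 6 libraries of a comparison alone, a replicate block, a fold threshold and each library left out in turn. Fits without the less deeply sequenced Nf1 null replicates 1 and 3, which leaves 1 library in that group, and without predicted genes and pseudogenes, were added after seeing the data.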

Results

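RNA levels were compared between 3 groups of cultured mouse cells, with 3 libraries in each: floxed Nf1 cells given GFP virus (GFP control), floxed Nf1 cells given Cre-GFP virus (Nf1 null), and floxed Nf1 and Arf cells given Cre-GFP virus (Nf1-Arf null). Nf1 encodes neurofibromin, a GTPase-activating protein that switches off RAS, and is the gene mutated in neurofibromatosis type 1. Arf is one of the products of Cdkn2a and stabilises p53 by binding Mdm2. The stated purpose was to see how these genotypes act on the transcriptome of Schwann cell precursors. Column totals were 34659213 to 36671330 normalized counts per library. The median SD between libraries of a group on the log2 scale was 0.11 in the GFP control, 0.262 in the Nf1 null and 0.108 in the Nf1-Arf null group, and the Nf1 null replicates 1 and 3 had the fewest reads.

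The normalized count of Nf1 was 1640, 1550 and 1830 in GFP control replicates 1, 2 and 3. It was 1770, 1280 and 1540 in the Nf1 null libraries and 1170, 1110 and 1200 in the Nf1-Arf null libraries. The Nf1 null group did not pass the test against the GFP control (log2 change -0.14, SE 0.12, adjusted p = 0.32), and Nf1 null replicate 2 had the lowest value of its group. Nf1 was lower in the Nf1-Arf null group than in the GFP control (log2 change -0.53, adjusted p = 0.00507) and than in the Nf1 null group (log2 change -0.39, adjusted p = 0.0146). This last call was lost without Nf1-Arf null replicate 2 (-0.36, adjusted p = 0.0508). Both Nf1 null comparisons also depended on which Nf1 null libraries were used. Without Nf1 null replicates 1 and 3, the log2 change was -0.38 for Nf1 null against GFP control. It was -0.14 there for Nf1-Arf null against Nf1 null. Cdkn2a was at 374, 344 and 426 in the GFP controls, at 3750, 3560 and 4280 in the Nf1 null libraries and at 768, 688 and 778 in the Nf1-Arf null libraries. Values per gene cover exons outside a deleted part, and Cdkn2a also encodes p16, so neither gene's level checks whether the floxed parts were removed.

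**Figure D1:**
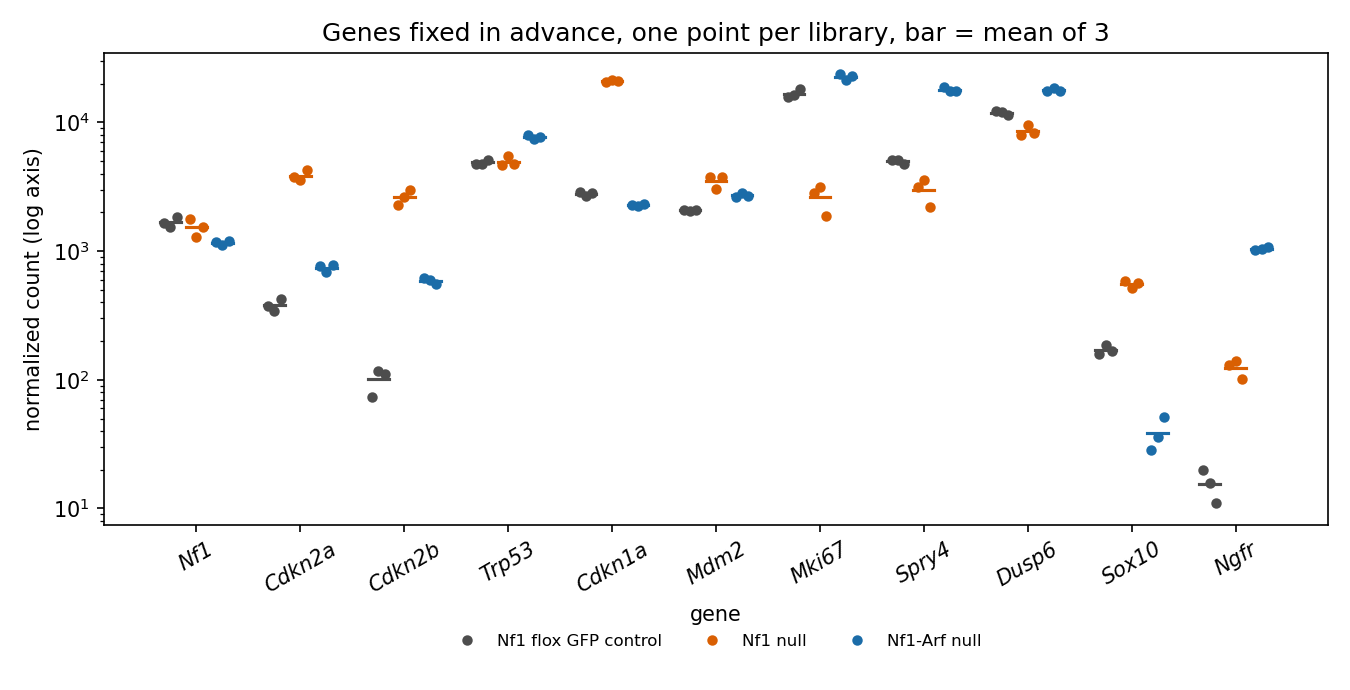
Normalized counts (log axis) of genes fixed in advance, by gene, with a point for each of the 9 libraries coloured by group and a bar at the mean of 3. Cdkn1a lies at 20500 to 21200 in the Nf1 null libraries, above the 2250 to 2860 of the other 6, while Nf1 lies between 1110 and 1830 in all 9.

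The groups also differed in transcripts that mark the sex of the cells and the state of the RNA. Xist, the RNA that coats the inactive X chromosome of female cells, was at 8.9, 14.6 and 4.1 in the GFP controls, at 12487, 8525 and 17210 in the Nf1 null libraries and at 232.8, 141.3 and 141.2 in the Nf1-Arf null libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in all 3 Nf1 null libraries. Their means in the GFP control were 1250, 1490, 732 and 502, and in the Nf1-Arf null group 1550, 1020, 1240 and 604. These sex-linked transcripts therefore move with the Nf1 null group in every comparison below that includes it. Mitochondrially encoded genes took 2.31 to 2.82% of the counts in the GFP controls, 3.65 to 5.22% in the Nf1 null and 0.78 to 1.19% in the Nf1-Arf null libraries. The nuclear RNA Malat1 was at 4256 to 5805, 60270 to 76630 and 2384 to 5123.

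**Figure D2:**
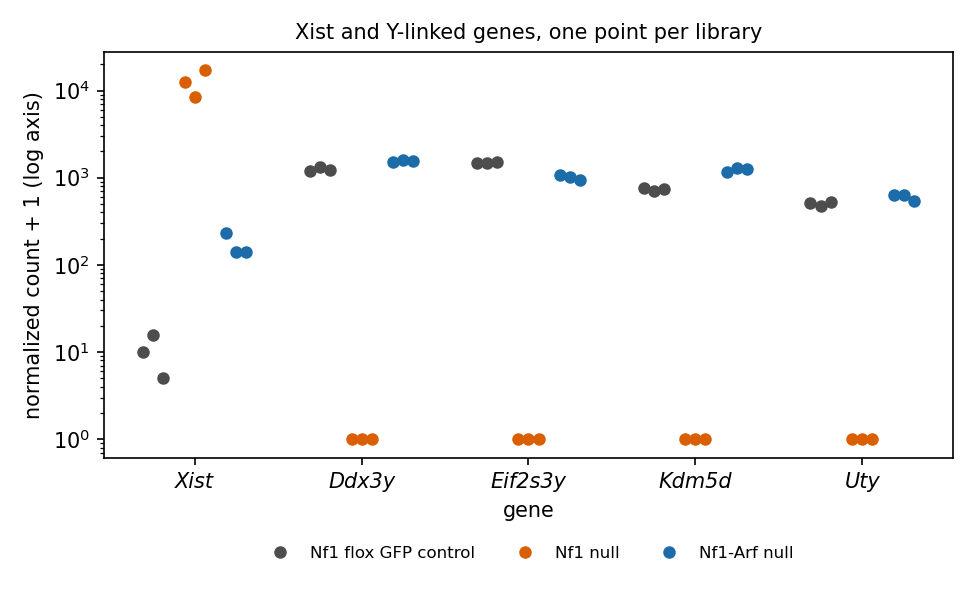
Normalized counts plus 1 (log axis) of Xist and 4 Y-linked genes, by gene, with a point per library coloured by group. The 3 Nf1 null libraries lie at 8525 to 17210 for Xist and at 0 for each Y-linked gene, while the other 6 libraries hold all 4 Y-linked genes.

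The list of glia and radial glia of the central nervous system, without genes that the Schwann cell lists share, had a median level of 1510 to 1530 in the GFP controls, 1470 to 2100 in the Nf1 null and 857 to 970 in the Nf1-Arf null libraries, and of 4000 to 4390, 3250 to 4060 and 1030 to 1040 with the shared genes. The median of the Schwann cell precursor list, without the gene shared with the first list, was 68.4 to 87, 256 to 285 and 52.8 to 65.1, and with that gene 115 to 137, 289 to 312 and 237 to 267, so the order of the GFP control and Nf1-Arf null groups turns on 1 gene. The list of immature and non-myelinating Schwann cells was at 1440 to 1630, 1870 to 2270 and 1400 to 1460, and at 669 to 925, 1240 to 1380 and 756 to 832 without the 5 genes shared with the first list. Olig1 and Olig2, transcription factors of the oligodendrocyte lineage, had GFP control means of 80500 ± 2420 and 34300 ± 558 (SD, n = 3). The glial glutamate transporter Slc1a3 was at 99990 ± 1978 there, and Sox10, a transcription factor of all Schwann lineage stages, at 171 ± 14.6. Olig2 and Slc1a3 were chosen after their values were seen.

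**Figure D3:**
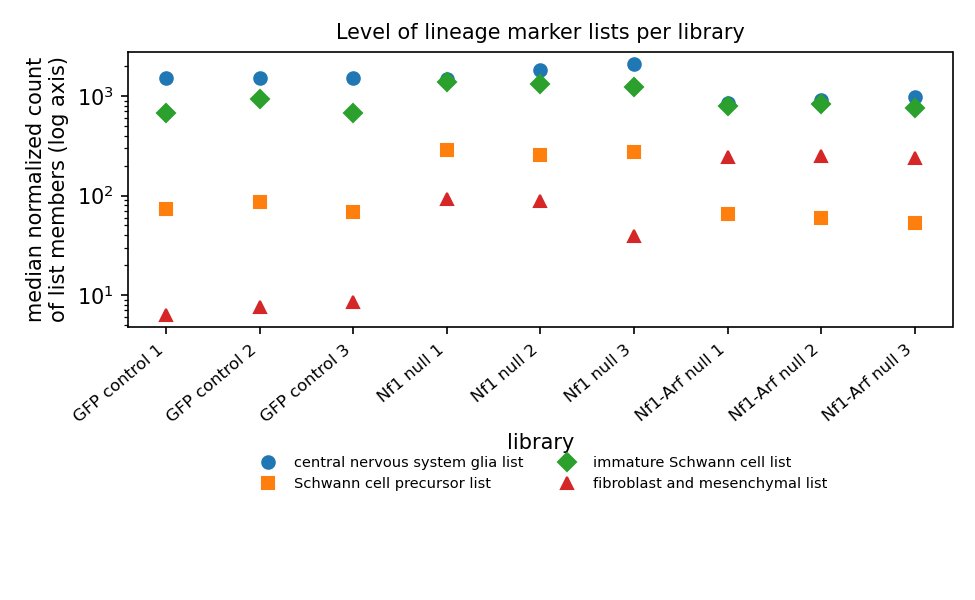
Median normalized count (log axis) of 4 marker lists in each of the 9 libraries. The circles of the central nervous system glia list (857 to 2100) lie above the squares of the Schwann cell precursor list (52.8 to 285) in every library and above the diamonds of the immature Schwann cell list without shared genes (669 to 1380), and the triangles of the fibroblast and mesenchymal list rise from 6.34 to 8.55 in the GFP controls to 241 to 247 in the Nf1-Arf null libraries.

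Comparing Nf1 null with GFP control cells would show what Cre-mediated loss of Nf1 does if the groups differed in nothing else. Their sex-linked transcripts differed too, and only the Nf1 null cells received Cre. No Cre-infected culture without floxed alleles was among the samples. The changes below therefore cannot be ascribed to Nf1 alone. Genes of DNA replication and mitosis were lower in the Nf1 null libraries. All 43 measured genes of the G1/S and DNA replication list fell, with a median log2 change of -3.15, and so did all 40 of the G2/M and mitosis list, with a median of -2.85. The camera adjusted p-values were 1.46e-15 and 1e-15, and with an estimated correlation the adjusted p-values were 0.02 and 0.144. Mcm5, a subunit of the replicative helicase, went from 7990 ± 362 to 185 ± 43.7 (log2 change -5.45, SE 0.14, adjusted p = 2.43e-09), and Ccne2, which encodes cyclin E2, from 1500 ± 173 to 34.8 ± 27.9. Foxm1, a transcription factor of mitotic genes, was 22-fold lower and the mitotic kinase gene Melk 16.3-fold lower. The proliferation marker Mki67 fell by 2.7 on the log2 scale (SE 0.16, adjusted p = 2.37e-07), from 16700 ± 1220 to 2620 ± 658. Cdkn2b, which encodes the inhibitor p15, rose from 101 ± 23.8 to 2630 ± 329 (26.2-fold, adjusted p = 1.76e-08), Cdkn2a rose 10.1-fold (log2 change 3.34, SE 0.11) and Cdkn1a, which encodes p21, rose 7.51-fold (log2 change 2.91, SE 0.05, adjusted p = 4.67e-10).

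Of 40 measured p53 target genes, 34 rose and 2 fell (median log2 change 1.12, camera adjusted p = 1.08e-09, and 0.0103 with an estimated correlation). Gdf15, a secreted stress cytokine, was at 0.302 ± 0.523 in the GFP control and 166 ± 95.6 in the Nf1 null group, and Mdm2 rose by 0.75 (adjusted p = 2.73e-05). Trp53 itself had a log2 change of 0.01 (adjusted p = 0.92; 0.28 with an adjusted p of 0.00508 after quantile scaling). All 30 genes of cholesterol and fatty acid synthesis fell, with a median of -2.31 and of -2.21 without the gene at 0 (camera adjusted p = 1.32e-15, and 0.0363 with an estimated correlation). Genes of ribosome biogenesis fell in 33 of 40 cases and rose in 2, as for the RNA helicase gene Ddx21 (8.27-fold lower), while 74 of 77 cytosolic ribosomal protein genes rose and 0 fell, with a median of 0.97. The adjusted p-value with an estimated correlation was 0.0815 for both of these lists. Rpl12 rose 3.67-fold and Rpl17, whose reads other genes share, 3.09-fold.

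Genes of inflammation and of the immediate early response were higher in the Nf1 null libraries, which also had the highest mitochondrial share. Of 27 interferon response genes 22 rose and 0 fell (median 2.11, camera adjusted p = 6.41e-06, and 0.02 with an estimated correlation), among them the chemokine gene Cxcl10 (52.4 ± 13.9 to 4010 ± 807). Of 15 antigen presentation genes 12 rose, including H2-Ab1 (42.7-fold), with an adjusted p of 0.0909 at an estimated correlation. Of 33 immediate early genes 27 rose and 3 fell (median 2.43), with an adjusted p of 0.0617 at an estimated correlation. Junb rose from 141 ± 3.24 to 5780 ± 344. Of 28 cytokine and NF-kB target genes 19 rose and 3 fell (adjusted p = 0.0719 with an estimated correlation), and Saa3, an acute-phase protein gene, was among the 5 largest rises (2.36 ± 3.25 to 855 ± 157). Macrophage and leukocyte markers rose for 10 of 11 measured genes, with a median of 3.91, and of 3.41 without the 4 genes at 0 in a group. With a pseudocount of 10 the median was 2.33. Levels were low: Lyz2, which shares sequence with Lyz1, reached 435 ± 93.5 and Mpeg1 84.5 ± 17.4. The scavenger receptor gene Marco, the third largest rise, was at 447, 502 and 385 and was listed at 0 in all 3 controls. The macrophage call (adjusted p = 0.0078) rose to 0.0815 with an estimated correlation and was lost without Nf1 null replicate 1, 2 or 3 (adjusted p = 0.121, 0.0975 and 0.119).

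Of 20 Schwann cell precursor markers 13 rose and 5 fell (median 1.64, and 1.58 without the gene at 0 in the control), and the camera adjusted p of 0.0387 became 0.275 with an estimated correlation and 0.0697 after quantile scaling. Sox10 rose 3.25-fold to 557 ± 36.5 (adjusted p = 0.000117) and the neurotrophin receptor gene Ngfr 7.67-fold to 124 ± 19.7. Erbb3, the neuregulin receptor gene, went from 5.13 ± 1.18 to 290 ± 44.2, and Foxd3, a neural crest transcription factor gene, from 0 in every control to 75.2 ± 40.9. Other members of the precursor list went down. Cdh19 went from 265 ± 34.6 to 64.9 ± 35.4, Itga4 from 870 ± 63.2 to 340 ± 31.6 and Ets1 from 4160 ± 172 to 1450 ± 140. Cdh19, Itga4 and Ets1 were chosen after their values were seen. Of 24 immature and non-myelinating Schwann cell markers 13 rose and 9 fell, with no call by camera (adjusted p = 0.146). Apod rose from 1.95 ± 0.922 to 274 ± 33.8 and Postn from 15.8 ± 4.34 to 1570 ± 289, while Olig1 fell by 1.48. Central nervous system glia markers fell in 13 of 20 cases and rose in 4 (median -0.51, adjusted p = 0.064). Large rises were among them, as Aqp4 went from 627 ± 60.6 to 11100 ± 621 and Gfap from 107 ± 27.3 to 2050 ± 150. Aqp4 and Gfap were chosen after their values were seen. Of 32 genes of RAS-MAPK feedback and output 17 rose and 10 fell (median 0.68, adjusted p = 0.0516, and 0.323 with an estimated correlation). That list was called after quantile scaling (adjusted p = 0.0318) and without GFP control replicate 3, Nf1 null replicate 1 or Nf1 null replicate 3 (0.0474, 0.0422 and 0.041). Its median was 0.42 with the filter minimum at 50. The MAPK phosphatase gene Dusp6 fell by 0.48 (adjusted p = 0.000154) and the RAS pathway inhibitor gene Spry4 by 0.77 (adjusted p = 0.000846).

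Extracellular matrix genes rose in 34 of 51 cases and fell in 9 (median 1.53, and 1.5 without the 3 genes at 0 in a group; camera adjusted p = 1.02e-05), with an adjusted p of 0.0719 at an estimated correlation. Col8a1 reached 190 ± 64.9 and was listed at 0 in all 3 controls. Hox genes, which set position along the body axis, rose in 23 of 37 cases and fell in 1 (median 1.12, and 1.04 without the 9 genes at 0 in a group; adjusted p = 0.02 with an estimated correlation). Hoxc11 was at 60.7 ± 20.3 against 0 in every control. Of 32 hypoxia and glycolysis genes 23 rose and 4 fell (adjusted p = 0.317 with an estimated correlation), with Ndrg1 203-fold higher. The other lists that camera called here lost their call with an estimated correlation. They were the fibroblast list (11 of 20 rose and 3 fell, adjusted p = 0.347, Col1a2 110-fold), the contractile list (10 of 15 rose and 3 fell, 0.12, Tagln 72.1-fold), NRF2 targets (18 of 27 rose and 3 fell, 0.12, Osgin1 52.5-fold) and apoptosis regulators (16 of 27 rose and 6 fell, 0.283, Fas 58.4-fold). Mitochondrially encoded genes (10 of 15 rose and 0 fell, 0.385, mt-Rnr1 13.1-fold), polycomb and chromatin regulators (17 of 31 fell and 7 rose, 0.158, Phf19 16.2-fold lower) and receptor tyrosine kinases and ligands (20 of 38 rose and 9 fell, 0.104) made up the rest. Quantile scaling ended the calls of the mitochondrial (adjusted p = 0.0608), receptor (0.0611) and polycomb (0.1) lists. Leaving out single libraries ended 4 of the calls. These were the fibroblast list without Nf1 null replicate 2 (adjusted p = 0.0568), the contractile list without Nf1 null replicate 1 (0.063), the receptor list without Nf1 null replicate 2 or 3 (0.0568 and 0.0923), and the polycomb list without Nf1 null replicate 2 or 3 or Nf1-Arf null replicate 2 or 3 (0.0889, 0.0758, 0.0502 and 0.0502).

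In total 10847 of 16020 genes differed between Nf1 null and GFP control, 5245 higher and 5602 lower, and 6172 of them by more than 1 on the log2 scale. The values of the groups did not overlap for 69.6% of genes, where chance gives 10%. Besides Marco and Saa3, the largest rises were Xist, the homeobox gene Nkx6-1 (612, 769 and 695, listed at 0 in all 3 controls) and Txnip, a thioredoxin inhibitor gene (136 ± 18.9 to 48300 ± 6250). The largest falls were the 4 Y-linked genes and the sialyltransferase gene St6gal2 (1110 ± 48.3 to 9.71 ± 16.8). Camera called 22 of 37 lists, 17 higher and 5 lower, and 5 kept their call with an estimated correlation. Adjusted over the list alone, the counts given were the same, except that 4 immediate early genes and 5 hypoxia genes fell.

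Comparing Nf1-Arf null with Nf1 null cells would show what loss of Arf adds to loss of Nf1 if the groups differed in nothing else. These groups also differed in sex-linked transcripts, so their differences cannot be ascribed to Arf alone. The cell cycle genes stood far higher in the Nf1-Arf null libraries. All 43 G1/S genes rose (median 3.83, camera adjusted p = 1.72e-15) and all 40 G2/M genes rose (median 3.08, camera adjusted p = 1.92e-15), with adjusted p-values of 0.0293 and 0.161 at an estimated correlation. Mcm5 rose 51.3-fold to 9370 ± 129, Ccne2 55.5-fold, Melk and Foxm1 both 18.1-fold, and Mki67 rose 8.84-fold (log2 change 3.14, SE 0.16, adjusted p = 6.05e-08). Cdkn1a was 9.14-fold lower at 2280 ± 43.3 (log2 change -3.19, SE 0.05, adjusted p = 2.09e-10), Cdkn2a was 5.17-fold and Cdkn2b 4.43-fold lower. Of 40 p53 target genes 34 fell and 3 rose (median -1.18, camera adjusted p = 1.11e-08, and 0.0146 with an estimated correlation), including Fas, the death receptor gene (1960 ± 81.9 to 26.8 ± 12.8). Mdm2 fell by 0.36 (adjusted p = 0.00361), and Trp53 rose by 0.66 (adjusted p = 1.86e-05).

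All 30 cholesterol and fatty acid synthesis genes rose (median 2.29 with and without the gene at 0 in a group, camera adjusted p = 1.73e-14, and 0.0721 with an estimated correlation). Ribosome biogenesis genes rose in 34 of 40 cases and fell in 0 (adjusted p = 0.0806 with an estimated correlation), with Ddx21 10.2-fold higher. Cytosolic ribosomal protein genes fell in 69 of 77 cases and rose in 3 (median -0.89, adjusted p = 0.115 with an estimated correlation), with Rpl34 3.96-fold higher. Immediate early genes fell in 26 of 33 cases and rose in 5 (median -2.35, adjusted p = 0.0801 with an estimated correlation), as for Fos (38.6-fold) and Junb (25.8-fold), while Nr4a3 rose 2.72-fold. Mitochondrially encoded genes fell in 14 of 15 cases (adjusted p = 0.212 with an estimated correlation), with mt-Rnr1 17.6-fold lower. Interferon response genes fell in 19 of 27 cases and antigen presentation genes in 13 of 15, with 0 rising in both lists and adjusted p-values of 0.0721 and 0.11 at an estimated correlation. Ifih1, a sensor of viral RNA, was 12.5-fold and H2-Ab1 21.9-fold lower. Macrophage markers fell in 8 of 11 cases and rose in 1, a call that an estimated correlation (adjusted p = 0.112), quantile scaling (0.0543) and leaving out Nf1 null replicate 1, 2 or 3 (0.409, 0.325 and 0.371) ended, with Lyz2 87.6-fold lower.

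Lineage genes differed as well. Central nervous system glia markers fell in 15 of 20 cases and rose in 2 (median -1.48, camera adjusted p = 2.78e-05, and 0.0801 with an estimated correlation), with Neurog2 96.7-fold lower. Immature Schwann cell markers fell in 17 of 24 cases and rose in 3 (median -1.34, adjusted p = 0.11 with an estimated correlation), with Scn7a 35-fold lower. Sox10 fell by 3.85 (SE 0.24, adjusted p = 2.54e-07) to 38.9 ± 11.8, while Ngfr rose by 3.07 (adjusted p = 2.25e-06) to 1040 ± 24.5. Of 20 neuron markers 10 rose and 9 fell, with no call by camera (adjusted p = 0.767), a median of -0.31 (-0.84 without the gene at 0 in a group), a mean of 0.05 and a downward test. That median was 0.25, 0.18 and 0.2 without Nf1 null replicate 1, 2 or 3, and -0.72, -0.86 and -0.87 without Nf1-Arf null replicate 1, 2 or 3. Dcx, a gene of migrating neurons, rose 21.1-fold and Ret 13.5-fold, and Ntrk3 fell 17.3-fold. Of 22 Wnt pathway targets 9 rose and 12 fell, with no call by camera (adjusted p = 0.679), a median of -0.38 (-0.55 without the gene at 0 in a group), a mean of 0.26 and a downward test. The median was -0.65 without Nf1-Arf null replicate 2 and 0.14 with the filter minimum at 50. There the Wnt effector gene Lef1 was 58-fold higher, and Rnf43 was 13.8-fold and Wif1 6.08-fold lower. Spry4 was 6.16-fold and Dusp6 2.09-fold higher, in a list of RAS-MAPK output with 12 of 32 genes higher and 14 lower (camera adjusted p = 0.648). Polycomb and chromatin regulators rose in 21 of 31 cases and fell in 6 (adjusted p = 0.0806 with an estimated correlation), with the maintenance DNA methyltransferase gene Dnmt1 8.76-fold higher. NRF2 targets (18 of 27 lower and 3 higher, adjusted p = 0.164 with an estimated correlation, Osgin1 37.3-fold lower) and cytokine genes (17 of 28 lower and 4 higher, 0.112, Mmp3 209-fold higher) were also called by camera. So were receptor tyrosine kinases and ligands (18 of 38 lower and 9 higher, 0.112), where the growth factor gene Igf2, whose transcripts share sequence, was 64-fold higher at 13500 ± 181. The receptor call was lost without Nf1 null replicate 1 or 3, Nf1-Arf null replicate 1 or 2 or GFP control replicate 1 (adjusted p = 0.0607, 0.105, 0.0592, 0.0504 and 0.0538) and after quantile scaling (0.0946).

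In total 11226 genes differed, 5894 higher and 5332 lower in Nf1-Arf null cells, 6762 of them by more than 1 on the log2 scale. Groups did not overlap for 71.8% of genes, where chance gives 10%. The largest rises were Kpna2 (0, 13.7 and 0 in the Nf1 null libraries and 5570 ± 199 in the Nf1-Arf null group, uncertain because of Gm10184), the Y-linked genes Ddx3y, Kdm5d and Eif2s3y, and Lrrc17 (806 ± 60.7, listed at 0 in Nf1 null replicates 1, 2 and 3). The largest falls were Pla2g7, a lipoprotein-associated phospholipase gene (9750 ± 761 to 8.6 ± 2.1), Marco (listed at 0 in all 3 Nf1-Arf null libraries), the claudin gene Cldn10 (736 ± 72.1 to 2.61 ± 2.74), Stmn4 (304 ± 14.1 to 0.463 ± 0.802) and the glutamate receptor gene Grin2b (502 ± 342 to 1.82 ± 2.59). Camera called 17 of 37 lists, 5 higher and 12 lower, and 2 kept their call with an estimated correlation. Of the counts given, a few differed when adjusted over the list alone: 18 immature Schwann cell markers fell, 22 polycomb genes and 5 cytokine genes rose, and 13 RAS-MAPK genes rose and 15 fell.

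**Figure D4:**
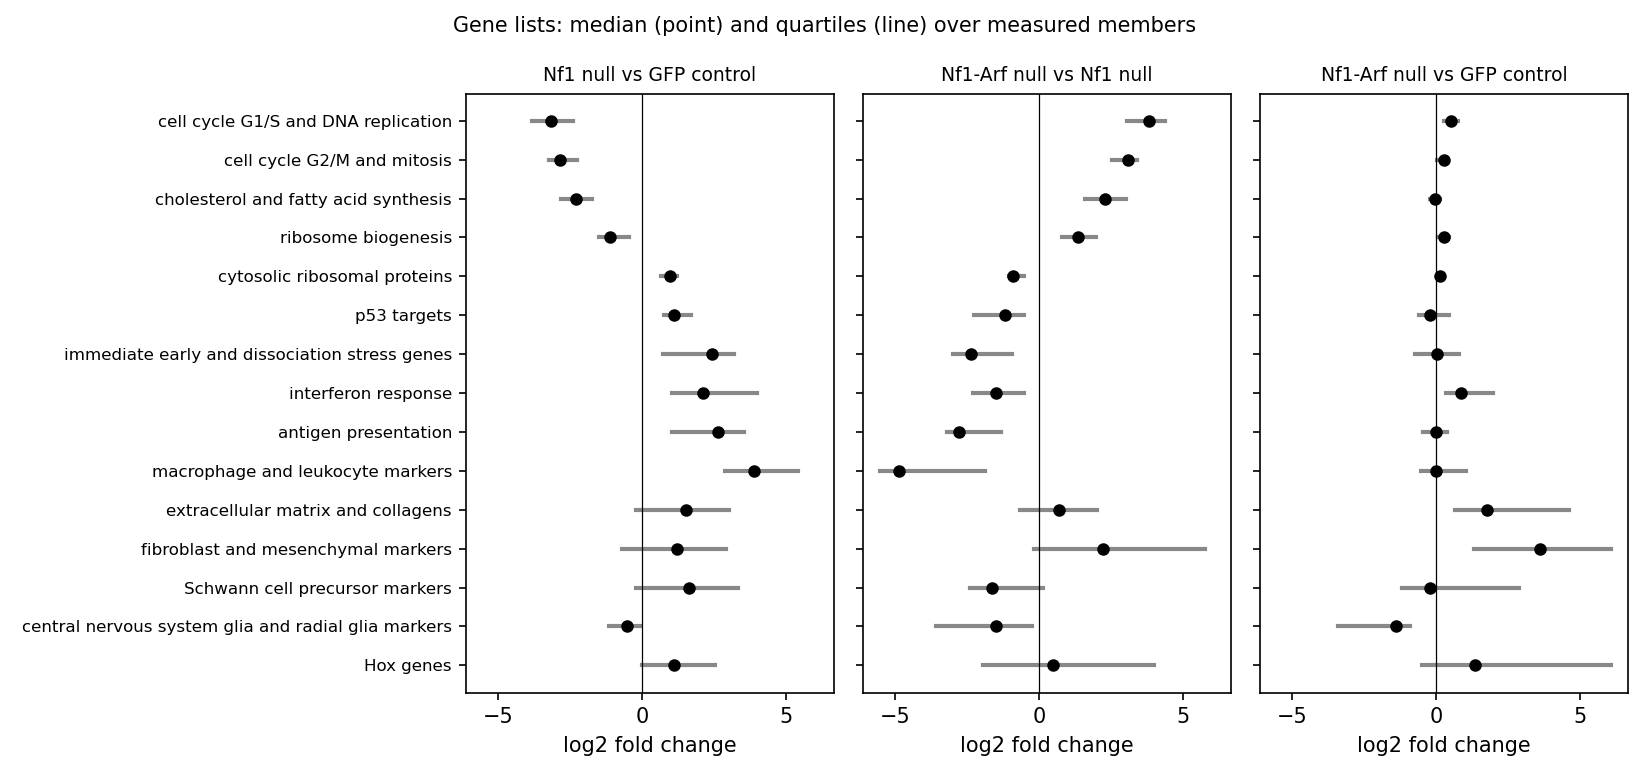
Log2 fold changes of 15 gene lists in the 3 comparisons, with a point at the median over measured genes and a line from the lower to the upper quartile. The cell cycle lists lie at -3.15 and -2.85 in Nf1 null against GFP control and at 0.51 and 0.27 in Nf1-Arf null against GFP control.

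Comparing Nf1-Arf null with GFP control cells sets the combined genotype against cells with neither gene cut. The controls did not carry floxed Arf or receive Cre. No GFP-infected culture of the Nf1-Arf genotype was analysed, so the changes below cannot be told apart from a difference of source or ascribed to the genotype alone. Genes of the extracellular matrix and of mesenchymal cells were higher and glial markers lower in the Nf1-Arf null libraries. Of 51 extracellular matrix genes 38 rose and 4 fell (median 1.77, and 1.59 without the 2 genes at 0 in a group; camera adjusted p = 2.06e-11, and 0.0403 with an estimated correlation). Col3a1, a fibrillar collagen gene, rose from 28.3 ± 20.5 to 53700 ± 3350 (log2 change 11.08, SE 0.4, adjusted p = 1.85e-08) and Col6a3 from 16.3 ± 19.1 to 4370 ± 221, while Tnr, a matrix gene of the central nervous system, was 6.96-fold lower. Of 20 fibroblast and mesenchymal markers 15 rose and 2 fell (median 3.61, camera adjusted p = 3.15e-06, and 0.173 with an estimated correlation), Pdgfrb 110-fold higher and Pdgfra 4.15-fold lower. Central nervous system glia markers fell in 16 of 20 cases and rose in 2 (median -1.4, camera adjusted p = 7.48e-10, and 0.0403 with an estimated correlation). Hes5, a Notch target, was 52-fold lower and the glutamate transporter gene Slc1a2 fell from 15900 ± 1060 to 587 ± 66.8, whereas Hes1 rose 1.67-fold.

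Hox genes rose in 22 of 37 cases and fell in 9 (median 1.36, and 0.5 without the 9 genes at 0 in a group; adjusted p = 0.0559 with an estimated correlation). Hoxc13 (2930 ± 112), Hoxc11 (2520 ± 125) and Hoxb13 (2720 ± 147) were among the 5 largest rises. Hoxc13 and Hoxc11 were listed at 0 in all 3 GFP controls, and Hoxb13 was at 0.302 ± 0.523. Ngfr rose 64.5-fold to 1040 ± 24.5 (adjusted p = 4.99e-08), and Sox10 fell by 2.15 (adjusted p = 5.01e-05). Immature Schwann cell markers fell in 11 of 24 cases and rose in 4, with a median of -0.37 and a mean of 0.26 (camera adjusted p = 0.0427 downward, and 0.268 with an estimated correlation). That call was lost without GFP control replicate 1 or Nf1-Arf null replicate 2 (0.0586 and 0.0515). The contractile list (10 of 15 rose and 2 fell, adjusted p = 0.164 with an estimated correlation, Rgs5 162-fold) and the endothelial list (6 of 10 rose and 1 fell, 0.173, Kdr 26-fold) were higher.

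**Figure D5:**
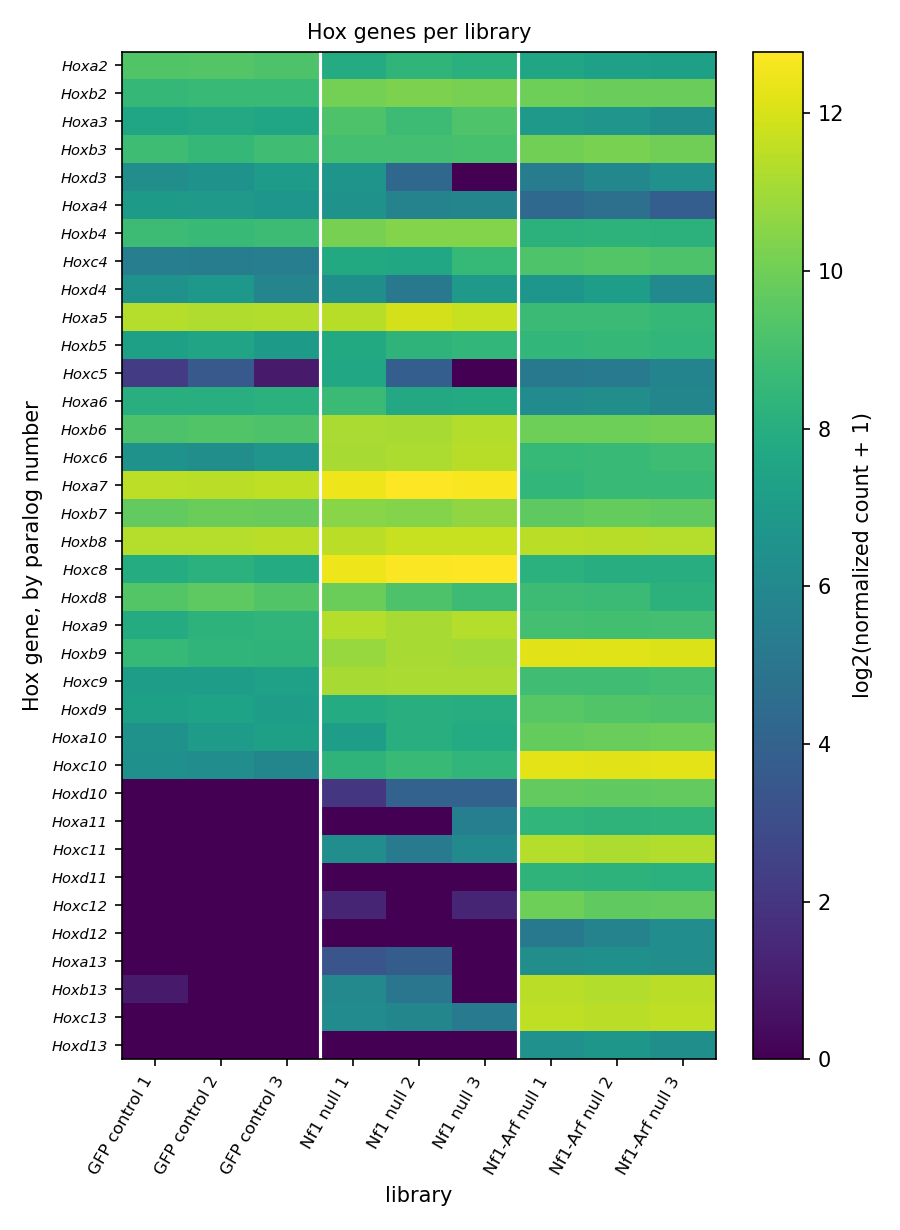
Log2 of the normalized count plus 1 (colour) for Hox genes, in rows ordered by paralog number, in each of the 9 libraries, in columns by group. All 12 measured genes of paralogs 10 to 13 have their highest mean in the Nf1-Arf null libraries, and 9 of them are listed at 0 in all 3 GFP controls.

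The cell cycle lists stood slightly above the control. Of 43 G1/S genes 20 rose and 0 fell (median 0.51, camera adjusted p = 0.000453, and 0.173 with an estimated correlation), the replication licensing gene Cdc6 2-fold (adjusted p = 0.0131, and 0.054 without GFP control replicate 2). As few as 12 G1/S genes rose among the alternatives. Of 40 G2/M genes 14 rose and 1 fell (median 0.27, camera adjusted p = 0.0429, and 0.806 with an estimated correlation), with Anln 1.68-fold higher. Without GFP control replicate 1 or 2 the G2/M call was lost (adjusted p = 0.0586 and 0.0774), and as few as 9 G2/M genes rose among the alternatives. Mki67 was 1.36-fold higher (adjusted p = 0.047), and this call was lost when any one of the 6 libraries was left out (adjusted p between 0.0638 and 0.131), without the filter (0.0666) and without a trend in the prior variance (0.0992). Cdkn1a fell by 0.28 (adjusted p = 0.00127), Cdkn2a rose 1.95-fold (adjusted p = 6.75e-05), Cdkn2b 5.91-fold (adjusted p = 2.08e-06), Trp53 1.58-fold and Mdm2 1.31-fold. Of 40 p53 target genes 11 rose and 19 fell, with no call by camera (adjusted p = 0.241), a median of -0.21 (-0.1 without Nf1-Arf null replicate 3), a mean of 0.07 and a downward test. Spry4 rose 3.6-fold (adjusted p = 4.36e-06) and Dusp6 1.5-fold (adjusted p = 7.83e-05), and of 32 RAS-MAPK genes 16 rose and 10 fell (camera adjusted p = 0.165).

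Of 32 hypoxia and glycolysis genes 25 rose and 2 fell (median 0.8, adjusted p = 0.268 with an estimated correlation). The lactate exporter gene Slc16a3 was 168-fold and Ndrg1 57.6-fold higher, and the aldolase gene Aldoc 9.51-fold lower. Of 22 Wnt pathway targets 9 rose and 10 fell, with no call by camera (adjusted p = 0.666), a median of -0.45 (-0.85 and -0.71 without Nf1-Arf null replicate 1 or 2), a mean of 0.65 and a downward test. Lef1 was 139-fold higher, Rnf43 11.5-fold lower and Axin2, a direct Wnt target, 3.9-fold lower. Mitochondrially encoded genes fell in 11 of 15 cases (adjusted p = 0.268 with an estimated correlation), with mt-Nd5 3.66-fold lower. Camera also called ribosome biogenesis (17 of 40 rose and 0 fell, adjusted p = 0.268 with an estimated correlation, Dkc1 1.71-fold), ribosomal proteins (32 of 77 rose and 1 fell, 0.458, Rpl34 4.29-fold) and interferon response (14 of 27 rose and 2 fell, 0.164, Oasl2 21.5-fold). The last were polycomb and chromatin regulators (17 of 31 rose and 2 fell, 0.164, Dnmt3b 2.67-fold) and the integrated stress response (15 of 33 rose and 4 fell, 0.267). There Gdf15 went from 0.302 ± 0.523 to 5.52 ± 1.55, a call lost with a pseudocount of 10 (adjusted p = 0.223). The stress response list lost its call without GFP control replicate 1, Nf1 null replicate 1 or 3 or Nf1-Arf null replicate 3 (adjusted p = 0.0514, 0.0619, 0.0735 and 0.0591). Among the alternatives as few as 12 ribosome biogenesis genes and 9 interferon response genes rose.

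In total 6906 genes differed between Nf1-Arf null and GFP control, 3596 higher and 3310 lower, 2792 of them by more than 1 on the log2 scale. Groups did not overlap for 66.2% of genes, where chance gives 10%. The other large rise was Nkx6-1 (1930, 1740 and 1650, listed at 0 in all 3 controls). The largest falls were Pla2g7 (3800 ± 532 to 8.6 ± 2.1), the histone gene H2ac12 (1540 ± 164 to 9.82 ± 15.6, uncertain because of its near copies), Rph3a (799 ± 31.3 to 1.89 ± 2.16), St6gal2 (1110 ± 48.3 to 5.32 ± 5.27) and Lhfpl3 (6560 ± 339 to 28.6 ± 3.31). Camera called 16 of 37 lists, 13 higher and 3 lower, and 2 kept their call with an estimated correlation. Adjusted over the list alone, 23 G1/S genes rose, 12 G2/M genes rose and 0 fell, 18 RAS-MAPK genes rose, 13 mitochondrial genes fell, 17 central nervous system markers fell, 12 immature Schwann cell markers fell, 7 endothelial markers rose, 15 interferon genes rose and 18 polycomb genes rose. The other counts given were the same.

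Over all 3 groups the F test called 12655 of 16020 genes. Among genes called in both comparisons against the GFP control, 1654 were higher and 1446 lower in both, and 2112 had opposite signs. Independent lists of the same sizes would share 1177, 1157 and 2341 genes. Simulated groups with no gene changed, set against simulated controls that they shared, had 0 called genes of the same sign in common, in the mean and at the highest of 100 draws. With nothing changed hardly any gene is called, so that 0 was to be foreseen and tests nothing. The simulation also gave all groups the same spread per gene and drew genes independently, unlike the data. Of all genes, 54.3% had the same sign in both comparisons, against 66.7% in the simulated groups. The correlation of log2 changes across genes, which are not independent replicates, was 0.318 against a simulated 0.498. With nothing changed and equal spread, the shared controls alone fix the simulated share of signs and the simulated correlation. Setting the observed values against them therefore does not show how far the groups agree. The covariance of log2 changes was 0.722 against a simulated 0.0977. With 3 controls no split that leaves at least 2 on each side was possible, so part of any excess may come from the shared controls. Correlations between libraries of different groups were 0.824 to 0.86 for GFP control with Nf1 null, 0.906 to 0.914 for GFP control with Nf1-Arf null and 0.8 to 0.837 for Nf1 null with Nf1-Arf null.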

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

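The fit without Nf1 null replicates 1 and 3, which had the fewest reads, and the fit without predicted genes and pseudogenes were chosen after seeing the data. The first leaves 1 Nf1 null library, assumed to vary like the other groups although the Nf1 null libraries varied most (median SD 0.262), so no call in the text rests on it. No count model was run, because whole reads could not be recovered for nearly all genes. Of 3191 alternative values for 147 gene results, 3164 kept their direction and their side of the threshold, 4 changed direction without a call in either fit, 21 lost the call, 2 gained it and 0 gained or lost it in the other direction. Of 1554 for 111 list results, 1401 kept both, 19 changed direction without a call, 90 lost the call, 41 gained it and 3 gained it in the other direction. Among genes with an adjusted p below 0.05, those changed by more than 1 on the log2 scale numbered 6172 (Nf1 null against GFP control), 6762 (Nf1-Arf null against Nf1 null) and 2792 (Nf1-Arf null against GFP control), fewer by construction. With an estimated correlation camera called 5, 2 and 2 lists in place of 22, 17 and 16. Fry, which asks another question of a list, called 33, 31 and 27. The 3 in the other direction were all by fry, upward where camera pointed down without a call: p53 regulators and the Arf network in Nf1 null against GFP control (adjusted p = 0.000551), Hox genes in Nf1-Arf null against Nf1 null (6.16e-07) and neuron markers in Nf1-Arf null against GFP control (0.0305).

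Leaving out 1 library at a time gave 9772 to 10940, 10104 to 11229 and 5589 to 8194 genes in the same order. For Nf1-Arf null against GFP control, settings that gave the variable Nf1 null libraries less weight called more genes than the 6906 of the fit to all 9. They were 9759 with sample weights, 9610 with the 6 libraries alone and 9603 without Nf1 null replicates 1 and 3. With replicate number as a block the counts were 10713, 11086 and 6628. Among results given in the text, that block ended the calls of the polycomb list in Nf1 null against GFP control (adjusted p = 0.0534) and, in Nf1-Arf null against GFP control, of Mki67 (0.0663), the stress response list (0.0534) and the immature Schwann cell list (0.0518). Deviations of libraries with the same number correlated between -0.023 and 0.015 over all genes, so they shared no broad shift. Pairing that touches only some genes is not excluded, and the labels do not mention any. Trp53 passed the test in Nf1 null against GFP control only after quantile scaling (0.28), and the cause was not tested. Nf1 null replicates 1 and 3, at about 22600000 and 23300000 reads, hold fewer reads behind low values than the other 7 libraries.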

Other observations

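The tests of the 3 patterns below were chosen after the results were seen, while the counts over other splits of the libraries were planned. Hox genes differed between the groups by their place in the clusters, a grouping by paralog number that was also chosen after the values were seen. The 12 measured genes of paralogs 10 to 13, which mark the caudal body, summed to 197 ± 16.8 normalized counts in the GFP control, 743 ± 63.3 in the Nf1 null and 16503 ± 586 in the Nf1-Arf null group (SD, n = 3). All 12 were higher in Nf1-Arf null cells than in either other group, and 9 were listed at 0 in every GFP control library. The 12 genes of paralogs 6 to 9 summed to 9336 ± 126, 30171 ± 1620 and 12230 ± 301, and 9 of them had their highest mean in the Nf1 null group. Hoxc8 was at 241.6, 289.1 and 228.7 in the GFP controls, at 5679.4, 6576.5 and 6998.2 in the Nf1 null libraries and at 281.4, 249.4 and 247.3 in the Nf1-Arf null libraries. The 13 genes of paralogs 1 to 5 summed to 5381 ± 75.6, 8228 ± 603 and 4244 ± 201. Over all 37 Hox genes, Nf1-Arf null against Nf1 null gave 16 higher and 17 lower, with a median of 0.48 (0.03 without the genes at 0 in a group) and a mean of 1.26 where camera pointed down (adjusted p = 0.865). The median was -0.24, -0.22 and -0.18 without Nf1-Arf null replicate 1, 2 or 3, so it gives no direction.

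In Nf1 null against GFP control, myelin genes rose in 9 of 18 cases and fell in 5 (camera adjusted p = 0.254). Neural crest markers rose in 9 of 21 cases and fell in 7 (0.661), and Notch pathway genes rose in 4 of 20 cases and fell in 11 (0.19). RAS GTPases and their regulators rose in 8 of 31 cases and fell in 14 (0.432), and YAP-TEAD targets rose in 10 of 22 cases and fell in 8 (0.551).

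With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each comparison only 1 split, the real one, gave as many genes. The real splits gave 10847, 11226 and 6906 genes, and the highest of the others 0, 1 and 0. Over all 3 groups, 1 of 100 splits gave as many genes as the real 12655, and the highest other gave 7215. Chance division of the libraries is thus unlikely there if they are independent, which the labels do not say. Libraries of a group made from the same culture would give this result whatever made the cultures differ.

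Xist was high and 4 Y-linked genes were at 0 in the Nf1 null libraries alone, while the Nf1-Arf null group held Xist at 1.35% of the Nf1 null mean and 18.7 times the GFP control mean. Loss of the Y chromosome from male cells leaves Xist low, and the lowest Nf1 null library held 928 times the GFP control mean, which argues against it. Labels swapped between groups of this series stay open, since 0 libraries of the other groups lacked Y-linked transcripts but an exchange of whole groups would leave none. Source embryos or cultures of different sex may also account for the pattern, but the 3 Nf1 null libraries are the pattern itself and no test of how it arose. A swap with cells from outside the series was not tested. By any of these routes, the libraries labelled Nf1 null hold high Xist without Y-linked transcripts, as female cells do. Those of the other groups hold Y-linked transcripts, so the groups as labelled differ in the sex of their cells. Every comparison with the Nf1 null group thus includes a difference of sex, and other differences of source stay open.

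Cell cycle genes were low in the Nf1 null libraries. The 83 genes had a median log2 difference from the GFP control mean of -2.95, -2.78 and -3.25 there, and the value of -2.78 belongs to replicate 2, sequenced as deeply as the controls, which argues against lower depth as the cause. A fall that follows Nf1 loss whatever the state of Arf would lower these genes in Nf1-Arf null cells against their own control, and against the GFP control the lowest of the 3 medians was 0.35. An Arf-dependent response to Nf1 loss could give the median difference of 3.25 between Nf1-Arf null and Nf1 null cells. Neither can be told apart from a difference of source, because no GFP-infected Nf1-Arf culture was analysed here and the sex-linked transcripts differed. An effect of Cre itself, which the GFP controls did not receive, was not tested.

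Central nervous system glial markers lay above Schwann cell precursor markers in all 9 libraries, although the labels describe root and ganglion cultures, while immature Schwann cell markers, at 669 to 1380 without shared genes, were nearer to them (857 to 2100). The lowest log2 ratio of the list medians, central nervous system to precursor, was 2.37 without shared genes (3.72 to 4.2 in the Nf1-Arf null libraries, but 1.96 to 2.13 there with the shared genes), which compares different genes without a pure culture of either type, so a small share of central nervous system cells stays open. Progenitors of the central nervous system making up a large part of the cultures is a candidate explanation that stays open too: the median percentile of the list among all genes tested was 86.3 to 89.5 in the GFP control and Nf1 null libraries but 59, 58.8 and 59.2 in the 3 Nf1-Arf null libraries. Of the 23 genes of that list, 5 are also in the Schwann cell lists and were left out. Drift of precursors towards a glial progenitor state in culture could not be tested, since 0 libraries have a passage number in the labels.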
